A study of Homo sapiens with 28 samples.

How the data were processed

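The deposited values were raw counts per peak, made by the authors from Fast-ATAC-seq libraries. Reads were aligned with Bowtie2, duplicates were handled with Picard and peaks were called with MACS2 on hg19, per the submitters' processing notes. The versions, the counting method, the read filters and the way peaks were pooled over libraries are not given in the sources used here. The values were whole numbers in all 28 libraries. Populations, donors and replicate numbers were taken from the labels.

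Peaks over the X inactivation centre (31) were left out, since levels there can tell a person's sex. The remaining 109914 peaks were filtered with filterByExpr of edgeR, which left 85271 tested and 24643 not tested. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR in a single fit of all 28 libraries with 1 term per population. P-values were adjusted by the Benjamini-Hochberg method over tested peaks within each comparison, with a threshold of 0.05. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9. Log2 CPM values for correlations and principal components used a prior count of 2.

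The comparisons were the 7 steps between neighbouring populations, P1 with P8, and any difference among the 8 populations. Single values per library were compared with exact two-sided permutation tests. Shares of the 1000 strongest peaks were computed after thinning each library to 500000 counts.

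Gene lists were written before the data were examined: globin, erythroid_TF, heme_iron, membrane_surface, late_maturation, epo_signalling, stem_progenitor, myeloid, megakaryocyte, lymphoid, cell_cycle and housekeeping. The design planned to link peaks to the nearest gene start, which needs an hg19 annotation that did not come with the data used here. Peaks inside hg19 windows around 34 loci, fixed before the data were examined, stood in for that link, so each list covers only some of its genes. Lists were tested with camera of limma at the preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the 96 tests. HBG1 with HBG2, and HBA1 with HBA2, are near-identical in sequence, so reads there are placed with less certainty.

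Peaks were named by a rule set before the data were examined. In each comparison the 5 largest rises and the 5 largest falls were named (10 and 10 for P1 with P8) among peaks past the threshold with fully separated groups and a mean level at or above the median of tested peaks, with at most 1 peak per neighbourhood of 50 kb. Within each list the loci with the lowest p were named, up to 4 for P1 with P8 and up to 2 elsewhere, and any globin or erythroid_TF locus. The rule had set these numbers for nearest genes. Without an hg19 annotation it named peaks by position only and used known loci only as background. Naming loci by their windows was therefore a later departure from it.

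The row order of the counts and the peak coordinates was checked by the correlation of neighbouring peaks (mean r 0.393, against 0.122 for distant ones, and 0.211 after shifting the coordinates by 1 row). Libraries sharing a donor and replicate number were compared after removing population means. The median r was 0.123 for such pairs and -0.0244 for others in P1 to P4, and 0.194 and -0.0675 in P5 to P8. In P1 to P4 each donor had 1 library per population, so donor and culture cannot be told apart there. In P5 to P8 the others mixed pairs of the same donor and of different donors. For P4 with P5 the medians were 0.225 and -0.0507, and for P1 with P8 0.00336 and -0.00019, with 2 such pairs each. The culture (donor and replicate number) was used as a block in an alternative fit.

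The alternatives were DESeq2 with its own size factors, those size factors within edgeR, library size alone, no filter on low counts, a mean of at least 20 counts, the culture as a block, counts summed per donor, the 2 populations of a comparison alone, glmTreat against a log2 fold change of 0.5, and leaving out each library in turn. The same code was tested on simulated data with 200 changed peaks per comparison. Motifs, peak classes and GC content were left out for want of a genome sequence.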

Results

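Chromatin accessibility was measured by Fast-ATAC-seq, which marks open DNA by transposase insertion after digitonin lysis, in 28 libraries of human erythroid cells. The cells were grown from CD34+ cells with erythropoietin, SCF and IL-3 and sorted by surface markers into 8 populations numbered P1 to P8. P1 to P4 were sorted on CD71 (the transferrin receptor) and CD235 (glycophorin), and P5 to P8 on CD49d (an integrin chain lost late) and Band3 (the anion exchanger). P1 to P4 had 3 libraries each, 1 from each of 3 donors, and P5 to P8 had 4 each, 2 from each of 2 donors. The analysis covered 109914 peaks of 250 bp in hg19, and the summed counts per library ranged from 520944 to 6034807 (median 2212208). By population the totals ran from 520944 to 2268839 in P1, 2196964 to 2468224 in P2, 2601334 to 3985386 in P3, 2047740 to 4078235 in P4, 1291493 to 6034807 in P5, 1267991 to 1990991 in P6, 1281890 to 5171252 in P7 and 1155297 to 2546629 in P8. P-values over libraries may be too small, since the P5 to P8 libraries shared 2 donors and the labels do not say whether replicates of a donor were separate cultures. All levels below are CPM, counts relative to the TMM-scaled total of the library, given as mean ± SD. Changes are log2 fold changes from edgeR ± SE. The SE was derived from the test, as the absolute log2 fold change divided by the square root of F.

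The first question was how far accessibility differed over the whole series. Of 85271 peaks tested, 61956 (72.7%) differed among the 8 populations at an adjusted p under 0.05. Among the 312 tested peaks in windows around 34 blood-cell loci, 257 differed. The highest mean lay in P1 for 17170 of the differing peaks (27.7%), in P8 for 8677 (14%) and in P7 for 7760 (12.5%), and in P6 for 2129 (3.44%). Libraries of the same population correlated at a mean Pearson r of 0.877 across peaks (36 pairs, 0.744 to 0.931), and libraries of different populations at 0.687 (342 pairs, 0.293 to 0.939). Peaks are not independent replicates, so no p-value is given. Some neighbouring populations had a mean r between the replicate values of the pair: 0.892 between P2 and P3 (0.875 and 0.922 within them), 0.874 between P5 and P6 (0.912 and 0.867) and 0.847 between P7 and P8 (0.884 and 0.845). The lowest Pearson r within a population was in P1 (mean 0.8), while by Spearman it was in P8 (0.75, against 0.803 in P1).

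**Figure D1:**
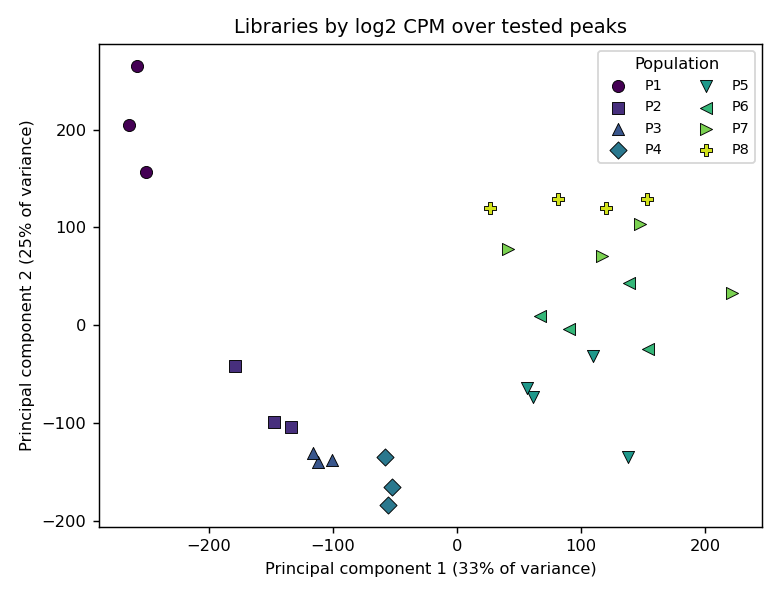
Principal components of log2 CPM over the 85271 tested peaks, with component 1 (33% of variance) on the x axis and component 2 (25%) on the y axis. Each point is 1 of the 28 libraries; the P1 libraries lay between -264 and -250.3 on component 1 and the P5 to P8 libraries between 26.44 and 222.1.

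The share of counts in the strongest peaks was higher in the late populations, though no comparison of it passed adjustment. After thinning every library to the same depth, the 1000 strongest peaks of each library held 8.66 ± 0.415% of counts in P1 (n = 3), 9.77 ± 0.835% in P4 (n = 3), 12.9 ± 1.48% in P5 (n = 4) and 16 ± 2.03% in P8 (n = 4). Without thinning the shares were 8.52% in P1 and 15.8% in P8. The difference between P1 and P8 gave an exact permutation p of 0.0286 (two-sided, 35 arrangements), the smallest this design allows, and 0.129 after adjustment over the 9 comparisons of this measure. These tests did not use the pairing by culture. From P2 over P3 to P4 the thinned share rose in replicate 1 (9.65, 9.814 and 10.7%). It rose likewise in replicate 2 (8.215, 8.421 and 9.088%) and replicate 3 (8.033, 8.474 and 9.517%). From P1 to P2 it rose in replicate 1 and fell in replicates 2 and 3.

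The widest comparison was between P1, which carried neither CD71 nor CD235, and P8, the most mature sort. The globin loci, which encode the haemoglobin chains, opened in most of their peaks. In the beta-globin locus control region, the distal enhancer cluster of that locus, the peak on chromosome 11 at 5305875 to 5306124 rose from 6.56 ± 3.45 CPM in P1 (n = 3) to 148 ± 53 in P8 (n = 4), a log2 change of 4.6 ± 0.45 (adjusted p = 4.09e-11). In the HBB cluster the peak at 5248208 to 5248457 rose by 4.80 ± 0.49 (adjusted p = 8.85e-11), from 4.17 ± 2.04 to 114 ± 42. Upstream of the alpha-globin genes, the enhancer peak on chromosome 16 at 163480 to 163729 rose from 12 ± 5.17 to 203 ± 64.1 (3.98 ± 0.39, adjusted p = 3.80e-11). All 5 tested peaks of the locus control region and 7 of the 8 alpha-globin enhancer peaks rose.

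Loci for the red-cell membrane, haem synthesis and late maturation followed the same direction from P1 to P8. At SLC4A1, which encodes Band3, all 6 peaks rose, led by chromosome 17 at 42343975 to 42344224 (4.61 ± 0.42, adjusted p = 8.49e-12, 4.12 ± 0.975 to 108 ± 34.3 CPM). At ANK1, which encodes the ankyrin that ties the membrane to its skeleton, 16 of 29 peaks rose and 0 fell under edgeR. At ALAS2, the first enzyme of erythroid haem synthesis, all 3 peaks rose, the largest by 5.09 ± 0.48 (adjusted p = 1.71e-11). At XPO7, a nuclear exporter active during terminal maturation, 12 of 14 peaks rose, and the peak on chromosome 8 at 21823546 to 21823795 went from 1.98 ± 0.544 to 62.5 ± 16.8 CPM (4.82 ± 0.44, adjusted p = 8.03e-12). At BCL2L1, which encodes the survival protein BCL-XL, 11 of 17 rose and 1 fell, and the leading peak, chromosome 20 at 30298324 to 30298573, rose by 5.43 ± 0.54 (adjusted p = 5.60e-11).

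Several loci of the progenitor and myeloid programmes lost accessibility between P1 and P8, and others were mixed. RUNX1, a transcription factor of blood progenitors, had 13 of 23 peaks falling and 1 rising. Its peak on chromosome 21 at 36421495 to 36421744 went from 37.2 ± 13 to 4.81 ± 2.41 CPM (-3.05 ± 0.36, adjusted p = 3.38e-09). SPI1, which encodes PU.1, a myeloid and lymphoid factor, had 5 of 8 falling, including chromosome 11 at 47381257 to 47381506 (-3.46 ± 0.45, adjusted p = 2.86e-08). MYB, a factor of proliferating progenitors, had 5 of 10 falling. The single peak at CEBPA, a granulocyte factor, fell from 50.3 ± 9.36 to 6.43 ± 4.62 CPM (-3.11 ± 0.37, adjusted p = 4.33e-09), and the single peak at MPO, a granule enzyme, fell by 2.70 on the log2 scale (adjusted p = 8.32e-04). CSF1R, with 7 of the 9 myeloid peaks, was mixed (1 rose, 3 fell). The region between HBS1L and MYB, which holds enhancers of MYB, had 3 of 19 peaks rising and 1 falling. GATA2 (4 of 6 falling), KIT (4 of 12 falling, 2 rising) and CD34 (1 of 3 rising) are named here after their values were seen.

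Erythroid transcription factors were mixed between P1 and P8. KLF1, the activator of beta-globin, had 4 of 5 peaks rising, led by chromosome 19 at 12998312 to 12998561 (2.94 ± 0.43, adjusted p = 2.69e-07). TAL1, a partner of GATA1, had 6 of 10 rising and 1 falling, and BCL11A, a repressor of fetal globin, 6 of 17 rising and 2 falling. At GATA1, the central erythroid factor, 2 of 5 rose. At LMO2, a bridging protein of the same complex, 3 of 13 fell and 1 rose. The largest rises outside the windows that the naming rule allowed included 8 peaks with 0 counts in all P1 libraries. The strongest of them, chromosome 16 at 71514933 to 71515182, stood at 34.5 ± 12 CPM in P8, at least 46.9-fold higher than a floor of 3 counts over the P1 group (0.736 CPM), and the others at least 14.7-fold to 34.8-fold higher. The largest falls the naming rule allowed included chromosome 7 at 27111289 to 27111538 (25.8 ± 5.85 to 0.647 ± 0.784 CPM, -5.09 ± 0.56) and chromosome 20 at 46356351 to 46356600 (69.3 ± 15.6 to 2.2 ± 1.96 CPM, -4.95 ± 0.47). Floors of this kind cover counting error only.

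**Figure D2:**
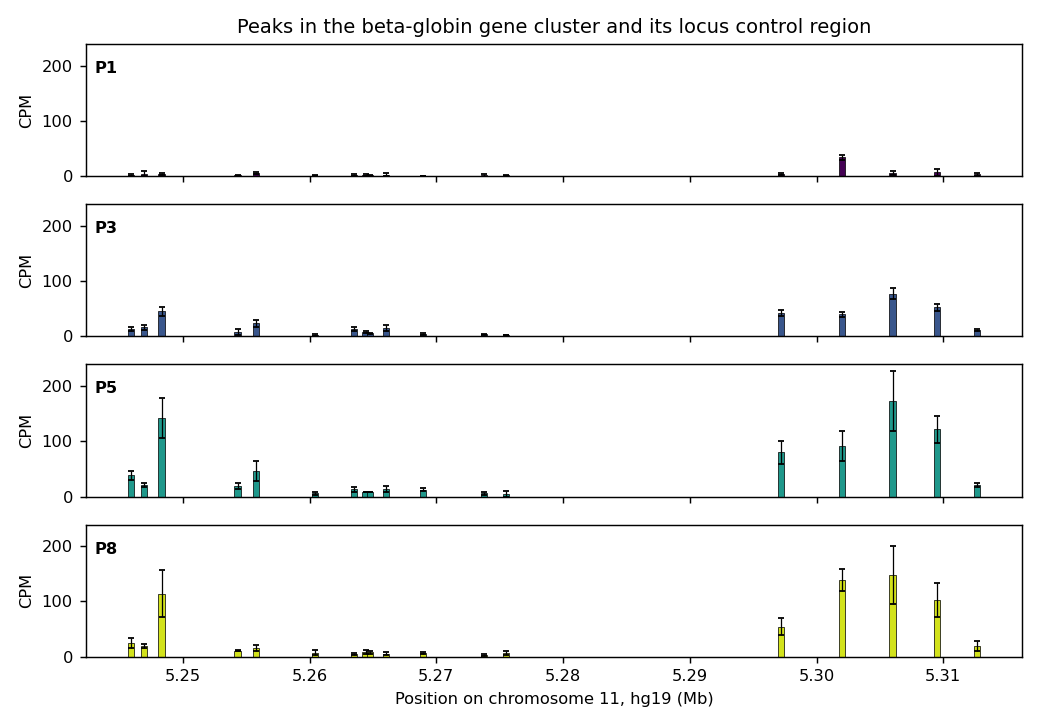
Mean CPM (y axis; bars, with SD) of the tested peaks in the beta-globin cluster and its locus control region by position on chromosome 11 (x axis, hg19, Mb) in P1 (n = 3), P3 (n = 3), P5 (n = 4) and P8 (n = 4). The peak at 5305875 to 5306124 stood at 6.56, 76.9, 173 and 148 CPM in these 4 populations.

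In total 36597 peaks changed between P1 and P8, 17268 up and 19329 down, with 43.3% of tested peaks fully separated between the groups (5.71% by chance). Scaling by library size alone left 36510 calls, of which 35.3% rose against 47.2% under TMM and 55% with a mean of at least 20 counts, and moved the median of all tested peaks to -0.37 from -0.01 on the log2 scale. No peak named above reversed direction under any scaling tried, which was likely from the start, since these peaks were chosen for strong changes. In simulated data with 200 changed peaks, the same test recovered 34% of 4-fold and 3% of 2-fold changes. With so few changed peaks the adjusted threshold is stricter than in this comparison.

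Gene lists were tested with camera, which ranks a list against all other peaks, on 12 lists and 8 comparisons (96 tests), of which 25 passed an adjusted p of 0.05 with the preset correlation. Only globin and membrane_surface from P1 to P8 also passed with a correlation estimated from the data (adjusted p = 0.0413 each). From P1 to P8 globin rose in 33 of 41 peaks and fell in 0 (34 and 0 adjusted over the list alone; adjusted p = 3.12e-17), and membrane_surface rose in 27 of 48 and fell in 0 (30 and 1 adjusted over the list alone; adjusted p = 4.34e-09). The late_maturation list rose in 23 of 31 and fell in 1 (23 and 1 adjusted over the list alone; adjusted p = 5.95e-09, adjusted p = 0.0991 with an estimated correlation). The stem_progenitor list fell in 32 of 81 and rose in 7 (32 and 8 adjusted over the list alone, adjusted p = 0.00932, adjusted p = 0.25 with an estimated correlation). The erythroid_TF list rose in 19 of 50 and fell in 6 (the same counts adjusted over the list alone, adjusted p = 0.0029, adjusted p = 0.356 with an estimated correlation). The heme_iron list rose in 4 of 12 and fell in 1 (the same adjusted over the list alone, adjusted p = 0.0357, adjusted p = 0.504 with an estimated correlation).

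Not called from P1 to P8 were myeloid (1 rose and 5 fell of 9, adjusted p = 0.154), cell_cycle, which held MYC peaks alone (0 rose and 4 fell of 7 under edgeR, 0.356), lymphoid (1 and 2 of 10, 0.497), epo_signalling at EPOR (2 and 1 of 5, 0.544), megakaryocyte at ITGA2B (0 and 1 of 5, 0.764) and housekeeping at ACTB and GAPDH (4 and 3 of 13, 0.978), with the same counts adjusted over each list alone. The MYC falls included chromosome 8 at 128747432 to 128747681 (23.8 ± 12.9 to 5.38 ± 2.78 CPM) and the ITGA2B fall was at chromosome 17, 42467181 to 42467430 (36.3 ± 11 to 7.25 ± 3.71). The fry test, which asks whether a list's peaks moved on balance one way without comparing them with other peaks, gave 1.60e-05 for myeloid, 0.00122 for cell_cycle and 0.0103 for lymphoid after adjustment. It gave 0.126 for epo_signalling, 0.151 for megakaryocyte and 0.945 for housekeeping. For lists called by camera, fry did not pass for globin from P2 to P3 (0.178) or late_maturation from P5 to P6 (0.133). Nor did it pass for heme_iron from P4 to P5 (0.151). From P3 to P4 fry passed neither globin (0.219) nor heme_iron (0.228) nor membrane_surface (0.256). The other lists called by camera passed fry. Among called lists the median, the mean and the test had the same sign. Among lists not called they differed in some cases: housekeeping from P1 to P8 had a median of -0.17, a mean of 0.07 and a test pointing down, and cell_cycle from P4 to P5 had 0.10, -0.30 and up.

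From P1 to P2 the cells gained CD71, and 26 of 41 globin peaks rose. At SLC4A1 1 of 6 peaks rose and at ANK1 12 of 29 rose and 1 fell. SLC4A1 at chromosome 17, 42343975 to 42344224, rose from 4.12 ± 0.975 CPM (n = 3) to 47.8 ± 1.48 (n = 3), a log2 change of 3.44 ± 0.43 (adjusted p = 1.68e-07). The locus control region peak at 5305875 to 5306124 on chromosome 11 rose to 59.6 ± 7.12 (3.29 ± 0.46, adjusted p = 7.32e-07), the alpha-globin enhancer peak at 163480 to 163729 on chromosome 16 to 76.5 ± 8.13 (2.57 ± 0.39, 2.71e-06) and the leading KLF1 peak to 25.5 ± 3.87 (2.93 ± 0.43, 1.81e-06). TFRC, which encodes CD71 itself, had 5 of 9 peaks rising and 1 falling, led by chromosome 3 at 195775278 to 195775527 (1.45 ± 1.77 to 16.3 ± 2.55 CPM). Between HBS1L and MYB 8 of 19 peaks rose and 0 fell, and the peak on chromosome 6 at 135439276 to 135439525 went from 2.46 ± 1.15 to 19.2 ± 3.02 (2.93 ± 0.48, adjusted p = 1.09e-05). In the same step the SPI1 peak at 47381257 to 47381506 on chromosome 11 fell from 33.3 ± 0.862 to 5.63 ± 4.19 (-2.58 ± 0.41, 7.21e-06), CEBPA fell by 1.65 on the log2 scale (2.17e-04) and 4 of 8 SPI1 peaks fell in all. At CSF1R, a macrophage growth-factor receptor, 2 of 7 rose and 2 fell, and the lowest p belonged to a rise at chromosome 5, 149434992 to 149435241 (2.78 ± 0.44, 5.96e-06).

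Outside the windows, the 5 largest rises from P1 to P2 that the naming rule allowed all had 0 counts in P1. Chromosome 2 at 127408652 to 127408901 stood at 12.5 ± 4.88 CPM in P2, at least 17-fold higher than the P1 floor, and the others at least 8.34-fold to 11.1-fold higher. The largest falls the naming rule allowed were at chromosome 1, 219262331 to 219262580 (36.4 ± 3.62 to 4.12 ± 5.79 CPM, -3.17 ± 0.48) and chromosome 16, 66780692 to 66780941 (69.3 ± 6.18 to 9.24 ± 9.96 CPM, -2.94 ± 0.39). In all 21662 peaks changed, 12203 up and 9459 down, and 40.1% of peaks were fully separated (10% by chance). The balance had no fixed direction: 56.3% of the calls rose, against 47.4% under DESeq2, 49.7% with its size factors in edgeR and 72.4% with a mean of at least 20 counts. Leaving out P1 replicate 3 gave 11770. Lists called up were globin (26 of 41 rose, 0 fell; 29 and 0 adjusted over the list alone; adjusted p = 2.05e-09, adjusted p = 0.104 with an estimated correlation), heme_iron (7 rose and 1 fell of 12, the same adjusted over the list alone; adjusted p = 8.65e-05, adjusted p = 0.138 with an estimated correlation) and membrane_surface (18 rose and 1 fell of 48; 19 and 1 adjusted over the list alone; adjusted p = 9.63e-05, adjusted p = 0.104 with an estimated correlation). The erythroid_TF list was called up as well (14 rose and 5 fell of 50; 15 and 5 adjusted over the list alone, adjusted p = 0.0207, adjusted p = 0.504 with an estimated correlation).

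From P2 to P3 and from P3 to P4, where CD235 appeared and rose, few peaks changed one step at a time. In the P2 to P3 step the alpha-globin gene peak on chromosome 16 at 229105 to 229354 went from 4.24 ± 3.47 to 9.07 ± 0.636 CPM (n = 3 each, adjusted p = 0.896 under edgeR), and 0 peaks passed under edgeR, 0 under DESeq2 and 4018 at an unadjusted p under 0.05. The 4018 are fewer than chance alone would give among 85271 tested peaks. With the culture as a block 44 peaks changed (3 up, 41 down), and leaving out P2 replicate 3 gave 2. The globin list was nevertheless called up (median 0.29; 0 of 41 peaks passed over all peaks and 0 adjusted over the list alone; adjusted p = 3.04e-05, adjusted p = 0.278 with an estimated correlation). The fry test did not call this list (0.178 after adjustment). In the P3 to P4 step the SLC4A1 peak at chromosome 17, 42345486 to 42345735, rose from 7.89 ± 2.67 to 27.6 ± 4.91 CPM without passing adjustment (1.81 ± 0.37, adjusted p = 0.0896).

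Only 4 peaks changed from P3 to P4 under edgeR (4595 at an unadjusted p under 0.05; 11 under DESeq2), and 544 with the culture as a block (374 up, 170 down). They were chromosome 5 at 180565749 to 180565998 (2.55 ± 0.43, 2.05 ± 1.21 to 12.2 ± 5.88 CPM), chromosome 10 at 134148979 to 134149228 (-2.09 ± 0.34), chromosome 13 at 31314425 to 31314674 (-1.89 ± 0.35) and chromosome 6 at 125403507 to 125403756 (2.30 ± 0.42, 3.18 ± 1.86 to 16 ± 7.08 CPM), the last chosen after its values were seen. The 4595 at an unadjusted p under 0.05 are little more than chance alone would give. The count of 4 fell to 0 without P3 replicate 1, P3 replicate 2 or P4 replicate 2, was 1 without P4 replicate 3 and 23 without P4 replicate 1. Of the calls 50% rose, against 73.7% by library size, 77.8% by DESeq2 size factors and 81.8% under DESeq2. The lists called up were globin (median 0.35; 0 of 41 passed and 0 adjusted over the list alone; adjusted p = 1.19e-05, adjusted p = 0.258 with an estimated correlation), heme_iron (median 0.27; 0 of 12 passed, 1 rose adjusted over the list alone, adjusted p = 0.00298, adjusted p = 0.278 with an estimated correlation) and membrane_surface (median 0.14; 0 of 48 passed, 4 rose adjusted over the list alone, adjusted p = 0.00441, adjusted p = 0.258 with an estimated correlation).

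Across both of these steps together, a comparison of P2 with P4 that was added after the data were seen, 3054 peaks changed (1768 up, 1286 down), and 310 without P2 replicate 1. With the culture as a block 7769 changed. SLC4A1 led the windows (chromosome 17, 42345486 to 42345735, 2.26 ± 0.40, adjusted p = 7.07e-04), followed by the alpha-globin genes (chromosome 16, 229105 to 229354, 2.13 ± 0.38, adjusted p = 7.99e-04). Fully separated peaks made up 13.1% from P2 to P3 and 15.5% from P3 to P4, against 10% by chance.

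The step from P4 to P5 joined the 2 sorting panels, so population and panel changed together. SLC4A1 and BCL2L1 opened further, while peaks between HBS1L and MYB mostly closed among those that passed. The stem_progenitor list as a whole was not called (3 rose, 12 fell of 81, adjusted p = 0.634 under camera). RUNX1 had 2 peaks rising and 1 falling. At SLC4A1 5 of 6 peaks rose and 0 fell, and the peak at 42345486 to 42345735 on chromosome 17 went from 27.6 ± 4.91 (n = 3) to 102 ± 19.9 CPM (n = 4; 1.90 ± 0.33, adjusted p = 3.06e-05). At BCL2L1 8 of 17 rose and 1 fell, led by chromosome 20 at 30298324 to 30298573 (11.2 ± 2.13 to 60.9 ± 14.4 CPM, 2.43 ± 0.35, 1.55e-06), and at XPO7 3 of 14 rose. The HBS1L to MYB peak at 135439276 to 135439525 on chromosome 6, which had opened from P1 to P2, closed again (25.6 ± 5.1 to 4.92 ± 1.11 CPM, -2.32 ± 0.33, 1.07e-06), 1 of 7 falls in that region beside 1 rise. LMO2 was mixed, with 2 of 13 peaks rising and 1 falling. The latter, at chromosome 11, 33906907 to 33907156, went from 34.7 ± 7.3 to 10.8 ± 4.22 (-1.65 ± 0.29, 3.31e-05), and PAX5, a B-cell factor, at chromosome 9, 36903726 to 36903975, fell from 9.81 ± 4.12 to 1.36 ± 0.683 (-2.95 ± 0.52, 4.65e-05). MYC was split, with 2 of 7 peaks rising and 2 falling, and MYB had 2 of 10 falling.

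Among all peaks from P4 to P5, chromosome 8 at 130705027 to 130705276 fell most (23.7 ± 1.32 to 1.16 ± 0.646 CPM, -4.24 ± 0.38, adjusted p = 8.30e-11) and chromosome 22 at 39538408 to 39538657 rose most (1.46 ± 1.26 to 18 ± 4.13 CPM, 3.76 ± 0.45, 2.97e-08) among those the naming rule allowed. In total 14611 changed, 4154 up and 10457 down, or 25608 (11475 up, 14133 down) with the culture as a block; 28% were fully separated (5.71% by chance). Leaving out P4 replicate 1 gave 8795. The median of all peaks lay at -0.10 under TMM and -0.28 under library size. Lists called up were globin (14 of 41 rose, 0 fell; 17 and 0 adjusted over the list alone; adjusted p = 2.60e-08, adjusted p = 0.135 with an estimated correlation), late_maturation (11 rose, 1 fell of 31; 12 and 1 adjusted over the list alone; adjusted p = 1.19e-05, adjusted p = 0.192 with an estimated correlation), membrane_surface (13 rose, 2 fell of 48; 14 and 3 adjusted over the list alone; adjusted p = 1.19e-05, adjusted p = 0.0991 with an estimated correlation) and heme_iron (3 rose, 0 fell of 12; 4 and 0 adjusted over the list alone, adjusted p = 0.0486, adjusted p = 0.504 with an estimated correlation). The lymphoid list was called down (0 rose, 2 fell of 10; 0 and 5 adjusted over the list alone, adjusted p = 0.0151, adjusted p = 0.135 with an estimated correlation). The erythroid_TF list was not called (8 rose, 4 fell of 50, adjusted p = 0.0752) but was with the culture as a block (adjusted p = 0.0184).

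**Figure D3:**
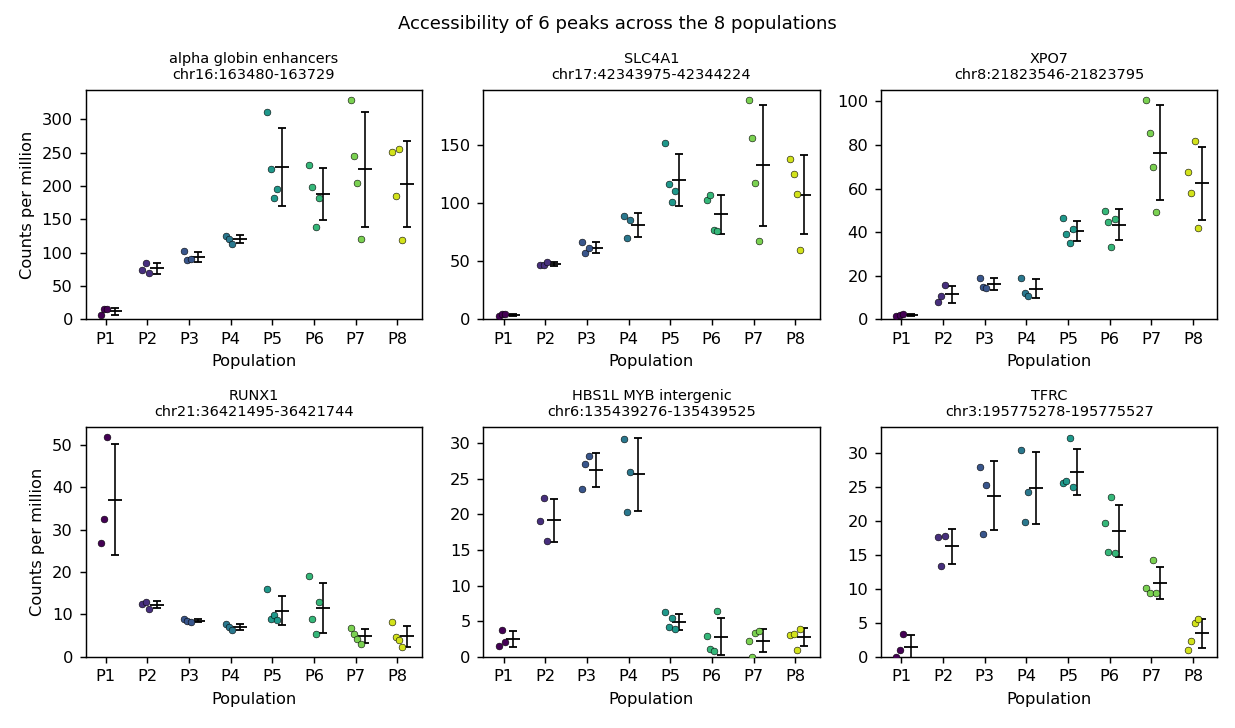
CPM (y axis) in each of the 28 libraries (points) with mean and SD (bars) for 6 peaks across P1 to P8 (x axis; n = 3 in P1 to P4, n = 4 in P5 to P8). The HBS1L to MYB peak stood at 2.46 CPM in P1, 26.2 in P3 and 4.92 in P5, while the SLC4A1 peak stood at 4.12 in P1 and 120 in P5.

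From P5 to P6, where CD49d fell and Band3 rose, most changed peaks fell. Chromosome 4 at 153551495 to 153551744 fell from 26.3 ± 13.7 to 2.22 ± 1.43 CPM (n = 4 each; -3.60 ± 0.46, adjusted p = 1.61e-05) and chromosome 4 at 35762553 to 35762802 from 24.8 ± 18.4 to 1.57 ± 0.0895 (-3.98 ± 0.52, 1.98e-05). Chromosome 12 at 89888253 to 89888502 rose from 2.64 ± 1.38 to 12 ± 6.1 (2.32 ± 0.42, 0.0011). BCL2L1 had 1 of 17 peaks rising (chromosome 20, 30287025 to 30287274, 1.41 ± 0.38, adjusted p = 0.0437) and CSF1R 1 of 7 falling (chromosome 5, 149482545 to 149482794, -1.27 ± 0.32, 0.0238). The BCL2L1 call ended without P5 replicate 1, P5 replicate 3, P5 replicate 4, P6 replicate 1 or P6 replicate 2 (adjusted p of 0.286, 0.108, 0.117, 0.0535 and 0.564 under edgeR). The log2 changes in these fits were 1.32, 1.35, 1.19, 1.43 and 0.89. This BCL2L1 call also ended with counts summed per donor (0.0944), at a log2 change of 1.46. It ended too with no filter (0.0833), the 2 populations alone (0.0699), glmTreat (0.2) and without the donor absent from P5 to P8 (0.0718). The CSF1R call ended without P5 replicate 1, P5 replicate 3, P6 replicate 2, P6 replicate 3 or P6 replicate 4 (0.204, 0.0688, 0.147, 0.0735 and 0.104). Its log2 change stayed between -1.27 and -1.12 in these fits. The CSF1R call ended under glmTreat too (0.186). The globin windows had 0 changed peaks under edgeR. In total 1261 peaks changed, 201 up and 1060 down, or 3398 with the culture as a block (9818 at an unadjusted p under 0.05); 5.11% were fully separated (2.86% by chance). The count was 132 without P5 replicate 1, 145 without P6 replicate 2, 817 without P6 replicate 3 and 2239 without P5 replicate 2. The late_maturation list was called up (1 rose, 0 fell of 31; 2 and 0 adjusted over the list alone, adjusted p = 0.00281, adjusted p = 0.386 with an estimated correlation).

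From P6 to P7 CD49d fell further, and 3 of 14 XPO7 peaks rose. The XPO7 peak on chromosome 8 at 21787320 to 21787569 had stayed between 1.60 and 3.75 CPM from P1 to P6 and rose to 22.1 ± 8.42 in P7 (n = 4; 2.49 ± 0.39, adjusted p = 4.91e-04). ANK1 had 2 of 29 rising, and the lower p was at chromosome 8, 41650011 to 41650260 (12.8 ± 4.48 to 32 ± 10.6 CPM, 1.30 ± 0.31, 0.0163). Elsewhere chromosome 6 at 37102399 to 37102648 rose from 7.45 ± 5.76 to 51.8 ± 17.2 (2.72 ± 0.35, 1.77e-05) and chromosome 1 at 205218334 to 205218583 from 24.8 ± 17.2 to 121 ± 51 (2.25 ± 0.34, 4.91e-04). Chromosome 1 at 50724007 to 50724256 fell from 30.3 ± 15.9 to 3.89 ± 3.38 (-2.71 ± 0.43, 4.91e-04). The late_maturation list was called up (3 rose, 0 fell of 31; 14 and 0 adjusted over the list alone; adjusted p = 5.07e-08, adjusted p = 0.104 with an estimated correlation). The cell_cycle list, MYC alone, was called down (median -0.58; 0 of 7 passed over all peaks and 0 adjusted over the list alone, adjusted p = 0.00693, adjusted p = 0.104 with an estimated correlation).

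In total 1322 peaks changed from P6 to P7, 746 up and 576 down (11366 at an unadjusted p under 0.05; 2100 under DESeq2; 136 with counts summed per donor), or 5092 (2955 up, 2137 down) with the culture as a block; 5.01% were fully separated (2.86% by chance). The share rising was 56.4% under TMM, 24.2% by library size (median of all peaks -0.11), 37.8% under DESeq2 and 42.5% with its size factors in edgeR, so the balance of gains and losses had no fixed direction. The count was 294 without P6 replicate 1, 349 without P7 replicate 2, 430 without P6 replicate 4, 537 without P6 replicate 3, 2055 without P7 replicate 4, 2093 without P7 replicate 1 and 2157 without P6 replicate 2. The ANK1 call ended without P6 replicate 1, P6 replicate 3, P6 replicate 4 or P7 replicate 2 (log2 changes of 1.36, 1.24, 1.12 and 1.11). It also ended with counts summed per donor (1.26).

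From P7 to P8, where CD49d was lost, the iron-uptake locus TFRC lost accessibility. It had 4 of 9 peaks falling and 0 rising, led by chromosome 3 at 195774695 to 195774944 (14.7 ± 6.41 to 2.55 ± 1.77 CPM, n = 4 each; -2.38 ± 0.39, adjusted p = 3.11e-04). CSF1R at chromosome 5, 149434992 to 149435241, fell from 60.5 ± 33.1 to 17.3 ± 9.45 (-1.88 ± 0.31, 3.41e-04). The largest rise the naming rule allowed was at ACTB, the cytoplasmic actin gene, at chromosome 7, 5570604 to 5570853 (22.2 ± 1.93 to 133 ± 108 CPM, 2.56 ± 0.36, 7.14e-05). Chromosome 15 at 33554582 to 33554831 fell from 22.5 ± 15.9 to 2.44 ± 1.38 (-3.11 ± 0.45, 1.19e-04), and chromosome 22 at 35772920 to 35773169 rose from 8.25 ± 3.16 to 27.6 ± 10.5 (1.84 ± 0.34, 6.76e-04). Of the globin windows 1 alpha-globin enhancer peak fell (chromosome 16, 169943 to 170192, -1.04 ± 0.27, 0.0176), a call that ended without P7 replicate 1, P8 replicate 2 or P8 replicate 4 (-0.84, -0.94 and -0.91). This call also ended with counts summed per donor (-1.09), the 2 populations alone (-0.97), glmTreat (-1.04) and without the donor absent from P5 to P8 (-0.96).

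In total 2861 peaks changed from P7 to P8, 159 up and 2702 down (11305 at an unadjusted p under 0.05), or 5079 (466 up, 4613 down) with the culture as a block; 4.81% were fully separated (2.86% by chance). The median of all peaks moved to 0.10 under library size from -0.02. When peaks with a mean of at least 20 counts were scaled and tested alone, 5152 changed and the balance was near even (2261 up, 2891 down). The count was 340 without P7 replicate 1, 1283 without P8 replicate 2, 1485 without P8 replicate 4, 1886 without P8 replicate 3 and 4422 without P7 replicate 4. Lists called down were heme_iron (0 rose, 5 fell of 12; 0 and 6 adjusted over the list alone; adjusted p = 8.59e-08, adjusted p = 0.0852 with an estimated correlation), globin (0 rose, 1 fell of 41, the same adjusted over the list alone; adjusted p = 2.09e-04, adjusted p = 0.364 with an estimated correlation) and membrane_surface (0 rose, 3 fell of 48; 0 and 8 adjusted over the list alone, adjusted p = 0.00515, adjusted p = 0.258 with an estimated correlation). The late_maturation list was not called (adjusted p = 0.0526) but was with the culture as a block (adjusted p = 0.0347).

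Many peaks that opened in the first step closed later. Of the 12203 peaks that rose from P1 to P2, 4191 fell from P4 to P5 and 959 rose again. Independent steps would give 1500 and 594, so both counts were above that, with 10457 falls and 4154 rises in that step. Of the 1060 peaks that fell from P5 to P6, 833 (78.6%) had risen from P1 to P2, and of the 2702 that fell from P7 to P8, 1541 (57%) had. Independent steps would give 152 and 387 here. These pairs of steps shared no library. A peak needs a level well above 0 to be called as falling, so the direction of the first step partly sets these counts. Examples named above were the HBS1L to MYB peak at 135439276 to 135439525 and, later, the TFRC peak at 195774695 to 195774944, which stood at 5.41 CPM in P1, 41.1 in P4 and 2.55 in P8.

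**Figure D4:**
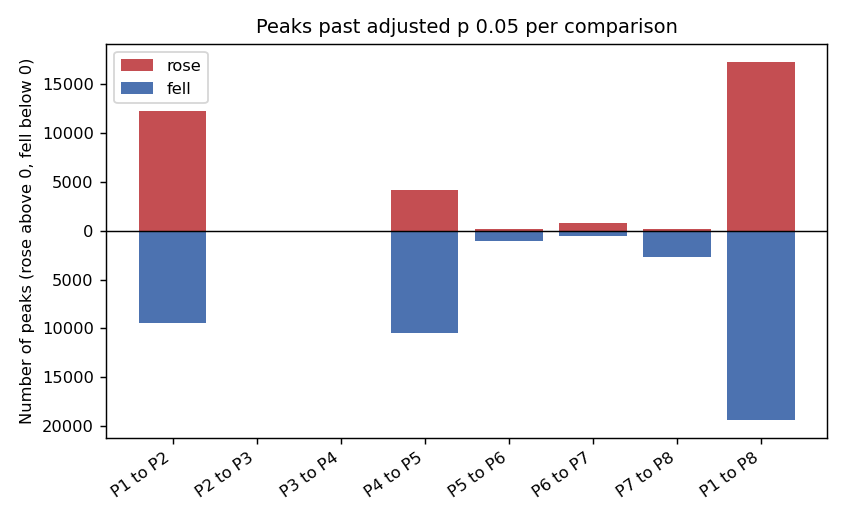
Number of peaks past an adjusted p of 0.05 under edgeR (y axis; rising peaks above 0, falling below) in each of the 8 comparisons (x axis). The steps P1 to P2 (21662) and P4 to P5 (14611) held most of the single-step changes, while P2 to P3 had 0 and P3 to P4 had 4.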

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

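Tests chosen only after the result was seen were the donor makeup of P4 and P5, the peak classes of P2 replicate 1 formed without P2 libraries, and the scaling of P7 and P8. Of 105 groups of 4 libraries examined for a library far from the others, 9 had one. The nominal rate is about 1 in 20. Many groups were peaks named for large changes in these same libraries, and libraries shared donors, so that rate may not hold. In total counts P8 replicate 3 stood at 2546629, against 1155297 to 1347700 in the other P8 libraries. P6 replicate 2 stood apart at 4 peaks: 24.9 CPM on chromosome 8 at 71042858 to 71043107 (others 5.86 to 6.46), 19.4 on chromosome 20 at 44407672 to 44407921 (4.4 to 5.66), 16.1 on chromosome 6 at 37102399 to 37102648 (4.04 to 5.13) and 2.77 on chromosome 7 at 30800951 to 30801200 (8.89 to 9.53). Its mean r was 0.895 with P7 and 0.876 with P6, and the other P6 libraries correlated more with P5 than with P6. Without P6 replicate 2 there were 145 changed peaks from P5 to P6 and 2157 from P6 to P7. The P8 libraries gave the other 4: 12.7 CPM on chromosome 19 at 11295004 to 11295253 in replicate 2 (19.2 to 20), 0.5 on chromosome 1 at 147994164 to 147994413 in replicate 3 (0 in the others), 3.17 on chromosome 18 at 42686435 to 42686684 in replicate 4 (0.796 to 1.01) and 7.09 on chromosome 2 at 129230741 to 129230990 in replicate 1 (1.5 to 2.39). The values near 0 among them rest on few counts, and no explanation of these single values was tested.

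The first pattern weighed was the large number of peaks changed between P4 and P5 (14611). Donor makeup as the whole cause is argued against, since 9497 peaks changed without the donor absent from P5 to P8. Unequal depth as the whole cause is argued against too, since 11268 changed with all P4 and P5 libraries thinned to 1291493 counts, against 15843 with these libraries alone and unthinned. The change of sorting panel cannot be told apart from the change of population, since 0 populations were sorted with both panels. A biological difference between P4 and P5 remains open as well. The real split gave 15843 peaks and the highest of the others 7137, and only 12 splits part as many pairs of the same culture, too few for a share under 0.05.

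The second pattern was the position of P2 replicate 1 between P1 and the other P2 libraries (mean r with P1 of 0.642, against 0.507 and 0.474). A lag shared by all sorted cells of this culture is argued against, since the highest share toward P1 in P3 replicate 1 and P4 replicate 1 of the same culture was 0.00709. P3 and P4 were themselves sorted on CD71 and CD235, so a lag of the culture that this sort removed would not show. Admixed P1 cells may account for part of it: the share toward P1 was 0.167 (95% bootstrap interval 0.164 to 0.217) from P1-high peaks and 0.309 (0.297 to 0.357) from P2-high peaks, a difference of -0.142, just inside the bound of 0.15 set beforehand. With classes formed without P2 libraries the shares were 0.201 and 0.302, a difference of -0.101. The intervals did not overlap in either version, but they resample peaks within 1 library. For P4 replicate 1 the intervals of the 2 classes did not overlap either (-0.0394 to -0.0315 and -0.168 to -0.122). They therefore cannot decide whether a single mixing share describes both classes. A P2 sort holding less mature cells remains open and untested.

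The third pattern was that peaks past the threshold mostly fell between P7 and P8 (2702 of 2861). The depth of P7 replicate 1 could account for part of the count, which was 1866 with this library thinned to 1832169 counts, just under the bound set beforehand, and 340 without it. A higher background in P8 remains open, since the 8527 peaks highest in P5 and P6 had a median log2 change of -0.161, between the bounds set beforehand, while the 8528 lowest had 0.352. Scaling remains open as well: the share that fell was 86.8% or more under library size and DESeq2 size factors but 56.1% when peaks with a mean of at least 20 counts were scaled and tested alone, a setting that also changes which peaks are tested. No biological explanation was tested beyond the change of population itself.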

How the results depend on the processing

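Alternatives chosen after seeing the data were leaving out the donor absent from P5 to P8, leaving out P1 replicate 1 and P2 replicate 1 together, and the comparison of P2 with P4. The locus windows were fixed beforehand, and their use in place of nearest genes was decided later, since an hg19 annotation was not used here. No named peak that was called reversed direction under any alternative run. These peaks were chosen because they passed in the main fit, many with fully separated groups, so a reversal was unlikely from the start. Of 179 calls at named peaks, 171 held under DESeq2, 170 under its size factors in edgeR, 170 under library size, 168 with no filter on low counts, 163 with counts summed per donor, 161 with the 2 populations alone, 148 under glmTreat and 158 without the donor absent from P5 to P8. With a mean of at least 20 counts 130 of 137 held, and leaving out single libraries 1113 of 1260. All 25 list calls held under library size and with the culture as a block, 682 of 700 when single libraries were left out, and 2 with an estimated correlation.

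With the culture as a replicate block more peaks changed: 44 from P2 to P3, 544 from P3 to P4, 25608 from P4 to P5, 3398 from P5 to P6, 5092 from P6 to P7 and 5079 from P7 to P8. All 179 calls at named peaks held with the block, and among lists it ended no call and added erythroid_TF from P4 to P5 and late_maturation from P7 to P8. The block takes differences between cultures out of the spread. Between P4 and P5 it rests on the 2 cultures that had libraries in both populations.

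A mean of at least 20 counts tests fewer peaks and gave 8518 from P1 to P2, 15487 from P1 to P8, 21 from P3 to P4, 7546 from P4 to P5, 23445 among the 8 populations, 5215 from P6 to P7 and 5152 from P7 to P8. The counts for P3 to P4, P6 to P7 and P7 to P8 rose although fewer peaks were tested, as did that for P5 to P6 (1406), and the cause was not tested. The glmTreat threshold asks for a larger change and gave 0 from P3 to P4, 8180 from P4 to P5, 343 from P5 to P6, 173 from P6 to P7 and 889 from P7 to P8. Counts summed per donor gave 37 from P3 to P4 and 136 from P6 to P7. Library size gave 19 and 3143 for the same steps, and DESeq2 11 and 2100. Its size factors in edgeR gave 9 from P3 to P4, and no filter gave 843 from P6 to P7. The 2 populations alone gave 21 from P3 to P4 and 1596 from P7 to P8. Without the donor absent from P5 to P8 there were 13391 from P1 to P2, 0 from P3 to P4, 9497 from P4 to P5 and 1680 from P7 to P8. This setting removed no P7 or P8 library, so that last count changed only through the scaling and spread shared with other populations. Spearman correlation within populations averaged 0.834. Apart from the stricter settings named and the P7 to P8 count without that donor, the cause was not tested.

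Leaving out single libraries gave 11770 to 21450 peaks from P1 to P2, 0 to 2 from P2 to P3, 0 to 23 from P3 to P4, 8795 to 15846 from P4 to P5, 132 to 2239 from P5 to P6, 294 to 2157 from P6 to P7, 340 to 4422 from P7 to P8, 26492 to 36477 from P1 to P8, 57085 to 63515 among the 8 populations, and 23 to 27 lists.

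Not run were the GC correction, the links to genes within 10 or 100 kb, promoter peaks alone, the motif window, and peak classes and motifs, for want of an hg19 sequence and annotation. In simulated data 2-fold changes were recovered in 2% to 8% of peaks and 4-fold changes in 34% to 62%, with 200 changed peaks in each comparison. The adjusted threshold is then stricter than in comparisons with many calls, so these shares bear mainly on the steps with few calls, where 2-fold changes at single peaks were mostly not detectable at this depth. The share of false calls was highest from P3 to P4 (8 of 73 calls) and from P5 to P6 (8 of 77). It stayed under 0.05 only from P7 to P8 (2 of 66) and from P1 to P8 (1 of 38).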

Other observations

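Other arrangements of the same libraries were tried for each comparison with its 2 populations alone. Among the 8 populations the real arrangement gave 61956 peaks and the others at most 2023. This argues against a random assignment of libraries, but these shuffles ignored donor and culture and cannot exclude that structure. From P1 to P8 the real split gave 36943 and the highest other 17552, and only 12 splits part as many pairs of the same culture, too few for a share under 0.05. The splits were too few for a share under 0.05 from P1 to P2 (25341, highest other 0), from P2 to P3 (0, highest other 7) and from P3 to P4 (21, highest other 15). Chance cannot be excluded by these counts from P5 to P6 (1174, highest other 1783), from P6 to P7 (975, highest other 1103) and from P7 to P8 (1596, highest other 2221), with 2 of 35 splits giving as many in each. For the first 2 of these steps the higher split was the one that set the donors apart, which reflects the structure of the donors. From P7 to P8 the donors-apart split gave 446. Among the 8 splits that part as many pairs of libraries of the same culture, the highest other counts were 0, 0 and 1 for these 3 steps, and with the culture as a block the real counts were 3398, 5092 and 5079. As many splits as the real one, itself included, numbered 1 of 10 from P1 to P2, 10 of 10 from P2 to P3, 1 of 10 from P3 to P4, 1 of 35 from P4 to P5 and from P1 to P8, and 1 of 30 among the 8 populations.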
